A study of Mus musculus with 18 samples.

How the data were processed

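Cerebella of WT and Chd4 cKO mice were cross-linked, lysed and sonicated, and chromatin was immunoprecipitated with antibodies against H3K4me3, H3K9/14ac or H3K27ac, per the labels' protocols. Libraries were sequenced on an Illumina HiSeq 2000. The series has 18 samples: 16 immunoprecipitated libraries in 8 groups of 2, and 2 inputs, which were not analysed here. BWA and the mouse build mm9 are named in the submitters' processing notes, without a version or further settings.

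The gene table holds, per the file headers, a score for each of 24 genes in each library, with 2 decimals. Scores go below 0 in each mark, so some background was subtracted or values were centred, but neither the step nor the scaling between libraries is stated in the labels or the headers. A score is not a read count, so depth and counting error are unknown, and no interval based on counts was computed. The curve table holds the authors' deposited mean score at each of 10001 positions from -5000 to 5000 bp of the TSS, for WT and cKO in 3 marks, with an error column for each. The header calls the error a standard error, but 100% of its values are whole multiples (within 0.001 of a step) of the step of an SD of 2 values with 3 decimals, about 50% of them odd. It was therefore used as a deviation between 2 libraries, and would be larger than the standard error by the square root of their number. Columns named WT without an age were read as P22, since the P6 columns are named as such.

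Of the 24 gene names, 23 matched a symbol of the GRCm38 reference table; clcf did not and is printed as listed. None of the 23 numeric identifiers in the table belonged to the gene named beside it, and 16 belonged to other genes, so they were not used. Chromosomes agreed for the 23 matched genes, and positions are printed as the table gives them, with mm9 as the build named in the submitters' processing notes. Fixed before the data were examined were 14 gene lists with 161 members; only 1 member, Nhlh1, from the list of early postmitotic and migrating granule neurons, is in the table, so no list was tested. The values of 1 promoter of the table are not reported here, although it stayed in the fits, counts and means.

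The design had assumed read counts, with limma on log2(value + pseudocount) as the stated choice for other units, and the latter was used. A pseudocount of 2 and a filter (score of at least 1 in at least 2 libraries of the mark) were set after the values were seen, and an exploratory fit with pseudocounts 1 and 2 preceded that choice. All libraries of a mark entered 1 limma fit (limma 3.58.1, R 4.3.3) without covariates, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Limma's estimate pooled the spread completely over promoters, so in these fits per mark each tested promoter has the same standard error. Fold changes are on the log2(score + 2) scale, which understates the change of low promoters. Mean scores per library were compared by exact two-sided permutation tests, which cannot give less than p = 0.33 with 2 libraries against 2. Differences between marks were tested as the interaction term of a separate limma fit, made on the libraries of the 2 marks and 2 groups concerned and on promoters passing the filter in either mark. Its standard errors therefore differ from those of the fits per mark and can vary between promoters. Overlaps were tested with Fisher's exact test. Promoters were named by a rule fixed beforehand: in a table this small, the 10 with the largest change in the P22 genotype comparison of each mark. Curves were averaged within 1000 bp of the TSS and in the outermost 10% on each side, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

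The fits were tested on simulated data with 200 draws per comparison, in which 4 promoters had a log2 change of 1 and 4 a change of 2. For the genotype comparisons, a change of 1 was called in 47.5% of cases for H3K4me3 (18 promoters), 89.4% for H3K9/14ac (22) and 96.3% for H3K27ac (21), and a change of 2 in 96.9%, 100% and 100%. Those draws had no library shifts. In 1000 simulations with no effect but with library shifts as large as those between replicates, as many calls as observed arose in 1.8%, 1.6% and 0% for the 3 genotype comparisons. As large a median change arose in 0.7%, 0% and 0%. The size of the shifts was taken as known, although it rests on few pairs of replicates per mark. Shares from these simulations may therefore be too low. The simulations used the promoters with values in all libraries, so Nt5dc2 was left out of them. On those promoters the age comparisons of H3K4me3 and H3K9/14ac had 4 and 2 calls; as many arose in 5.5% and 6.5% of simulations, and as large a median change in 81.6% and 95%. Alternatives tried were pseudocounts of 1 and 20, no filter, the replicate number as a block, fits of the 2 groups compared, scores without log, each gene's own spread, libraries centred on their median, each library left out in turn, 1 WT P22 library for each of the age and genotype comparisons, and other windows, flanks and smoothing for the curves. Where a group was left with 1 library, it was assumed to vary like the other groups.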

Results

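Histone marks of active promoters were mapped by chromatin immunoprecipitation sequencing in the mouse cerebellum. The marks were trimethylated lysine 4 of histone H3 (H3K4me3), acetylated lysines 9 and 14 (H3K9/14ac) and acetylated lysine 27 (H3K27ac). Wild-type (WT) mice were compared with conditional knockouts (cKO) of Chd4, the ATP-dependent remodeling subunit of the NuRD complex, at postnatal day 22 (P22), with 2 libraries per mark and genotype. H3K4me3 and H3K9/14ac were also measured in WT mice at postnatal day 6 (P6), again in 2 libraries each. The authors' table gave a score around the transcription start site (TSS) of 24 genes in 16 libraries, and a table of curves gave the mean signal around TSSs at P22. Scores ran from -0.82 to 67, and neither the read depth behind them nor the way the 24 genes were chosen is given in the sources used here. Counts over these genes are therefore not genome-wide shares, and if the genes were picked on these libraries, their direction is not independent evidence. Chd4 itself was not among the 24 genes, so the genotype labels were not checked here. Nothing in the labels says that the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

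The first question was whether H3K4me3 at these promoters differs when Chd4 is lost. H3K4me3 rose in the cKO at 9 of the 18 promoters tested and fell at 0 (limma, Benjamini-Hochberg adjusted). The change was largest at Nhlh1, a basic helix-loop-helix transcription factor gene of newly postmitotic neurons. Its score was -0.28 ± 0.31 in WT and 26.0 ± 8.99 in cKO (SD, n = 2 each), a difference of 4.00 ± 0.43 (SE) on the log2(score + 2) scale with limma adjusted p = 7.8e-12. The table places Nhlh1 on chromosome 1 at position 173987694. Cda, which encodes cytidine deaminase (chromosome 4, position 137923870), went from 1.11 ± 0.48 to 20.9 ± 9.78, a log2 change of 2.82 with limma adjusted p = 1.3e-07. As3mt, the arsenite methyltransferase gene, rose from 2.81 to 14.6, and Oprl1, the nociceptin receptor gene, from 3.12 to 15.5 (log2 changes 1.77 and 1.74). Ripk4, a kinase gene of keratinocyte differentiation, rose from 7.88 to 27.5, and Elavl2, a neuronal RNA-binding protein gene, from 0.24 to 4.15 (log2 changes 1.53 and 1.46). Smaller rises passed the test at Syde1, a GTPase-activating protein gene, at the promoter listed as clcf, and at the immediate early gene Arc (log2 changes 1.15, 1.08 and 1.06). Cplx3, a complexin gene, was at 0.18 in WT and 1.90 in cKO, a log2 difference of 0.81 with limma adjusted p = 0.112. Timp2 and Duox2 differed by 0.32 and 0.12, less than the SE of 0.43. Casq1, Gnb3, Hmcn2, Mslnl and Cpne6 fell under the H3K4me3 filter; without it Cpne6 rose by 1.13 (limma adjusted p = 0.0115) and Arc no longer passed (limma adjusted p = 0.0804). The median log2 change of the 18 promoters was 0.94. After each library was centred on its own median, 4 promoters were higher in the cKO (Nhlh1, Cda, As3mt and Oprl1) and 1, Pde1b, was lower. Leaving out WT replicate 1 left 5 calls, losing Arc, clcf, Ripk4 and Syde1, and leaving out cKO replicate 2 left 6, losing Arc, clcf and Syde1. The latter lowered the median change to 0.49 and the changes of Arc, clcf and Syde1 to 0.47, 0.66 and 0.74, while without cKO replicate 1 Arc changed by 1.65 and Cplx3 passed with 1.11. Without WT replicate 1 the change of Arc was 0.70. Calls also numbered 5 with a pseudocount of 20, 3 with the spread of each gene taken alone, and 0 without a log scale.

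H3K9/14ac was higher in the cKO at 18 of 22 promoters tested and lower at 0 (limma, Benjamini-Hochberg adjusted). Nhlh1 again changed most, from 0.46 ± 0.37 in WT to 12.7 ± 2.28 in cKO (SD, n = 2 each), a log2 change of 2.58 ± 0.28 (SE) with limma adjusted p = 3.4e-12. Cda rose from 1.58 to 13.0, Ripk4 from 0.98 to 7.50 and Elavl2 from 0.40 to 4.98 (log2 changes 2.04, 1.66 and 1.54). Casq1, the calsequestrin gene best known from skeletal muscle calcium stores, rose from 0.71 to 6.12 and As3mt from 1.02 to 6.70 (log2 changes 1.53 and 1.51). The promoter listed as clcf, Oprl1, Smoc1 (a secreted calcium-binding matrix protein gene) and Arc followed, with log2 changes of 1.29, 1.13, 1.06 and 1.00. At the other end stood Pde1b, Timp2, Duox2 and Hmcn2, with log2 differences of 0.52, 0.51, 0.43 and 0.19 and limma adjusted p from 0.0780 to 0.498. The median log2 change was 0.95, and centring the libraries on their medians turned the split into 3 promoters higher (Nhlh1, Cda and Ripk4) and 7 lower. Among the 7 were Cpne7, Gnb3 and Scn3b, which were called higher without centring. Calls numbered 10 without WT replicate 1, among others no longer including Arc and Syde1, and 14 without cKO replicate 2, where the change of Arc was 0.66. They numbered 11 with the spread of each gene taken alone.

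H3K27ac rose at 20 of 21 promoters tested in the cKO and fell at 0 (limma, Benjamini-Hochberg adjusted). Scores at Nhlh1 were 0.27 ± 0.43 in WT and 12.4 ± 1.95 in cKO (SD, n = 2 each), a log2 change of 2.68 ± 0.23 (SE) with limma adjusted p = 1.6e-13. Elavl2 went from -0.22 to 5.12 and Cda from 1.51 to 12.0 (log2 changes 2.00 and 1.99). Ripk4 scored 0.025 in WT and 5.22 in the cKO, while Casq1 rose from 1.67 to 10.2 (log2 changes 1.83 and 1.70). As3mt, the G protein beta subunit gene Gnb3, the promoter listed as clcf, the copine gene Cpne6 and Syde1 changed by 1.45, 1.36, 1.31, 1.16 and 1.11. The hemicentin gene Hmcn2, the 1 promoter that missed the threshold, scored 3.96 in WT and 5.90 in cKO, with limma adjusted p = 0.0803. The median log2 change was 1.06. With centred libraries 5 promoters were higher in the cKO (Nhlh1, Elavl2, Cda, Ripk4 and Casq1) and 6 were lower. Among the 6 were Arc, Oprl1, Pde1b and Timp2, which were called higher without centring. Calls numbered 17 without cKO replicate 2 and 15 without WT replicate 2, and each of these lost Arc, Pde1b and Timp2. With the spread of each gene taken alone they numbered 8.

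**Figure D1:**
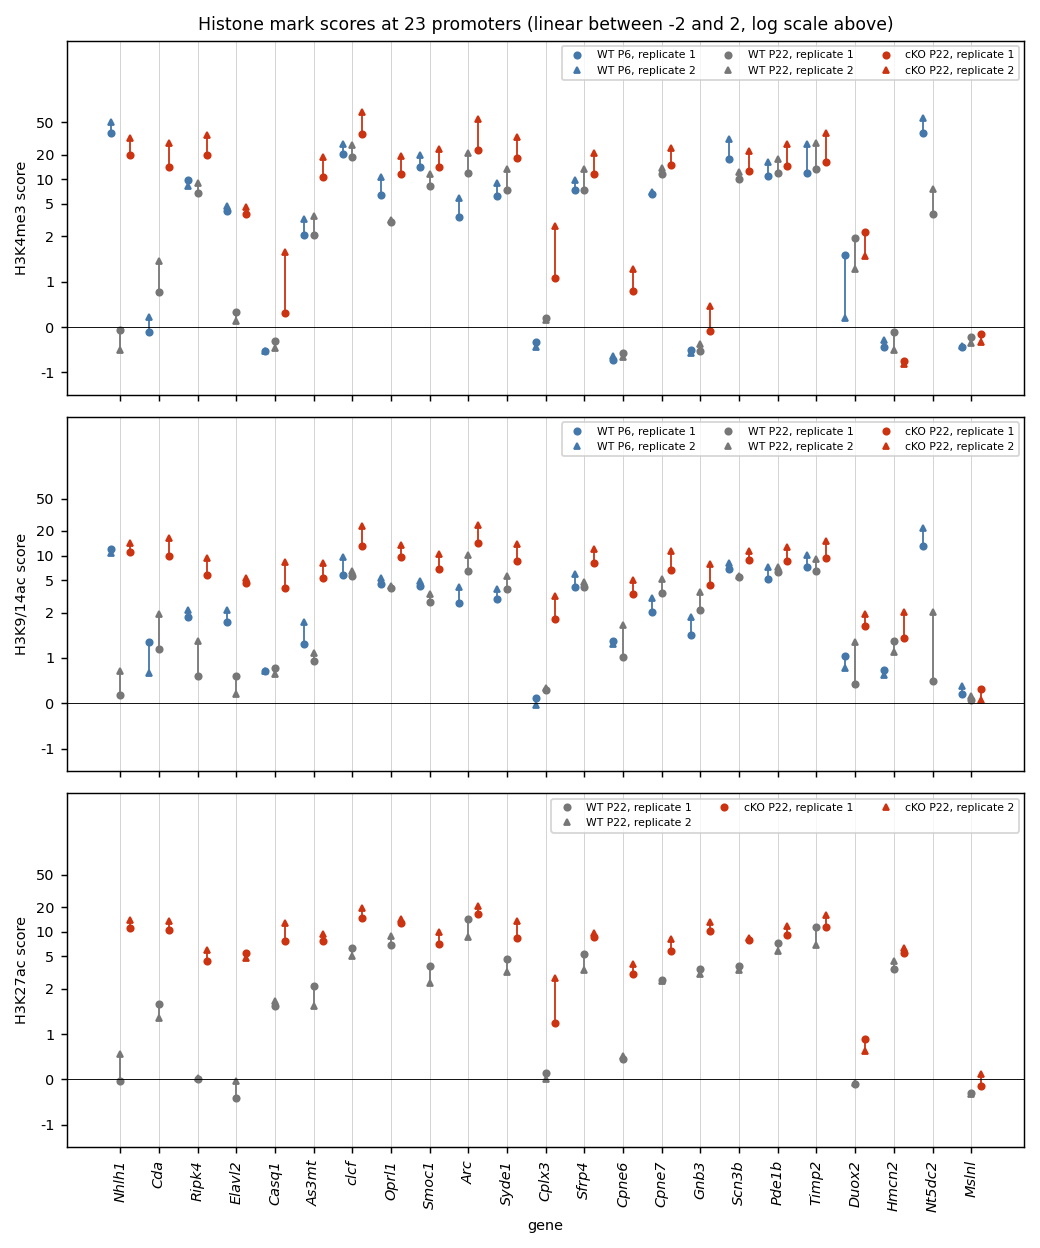
Scores of H3K4me3, H3K9/14ac and H3K27ac (vertical axes, score units, linear near 0 and logarithmic above) at each of 23 promoters in WT P6, WT P22 and cKO P22 libraries; each symbol is 1 library and each bar joins the 2 libraries of a group. At Nhlh1 the WT P22 libraries lie near 0 in all 3 marks, while the cKO means are 26.0, 12.7 and 12.4.

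Across the table, 9 promoters were called higher in all 3 marks: Nhlh1, Cda, As3mt, Oprl1, Ripk4, Elavl2, Syde1, Arc and the one listed as clcf. Without H3K4me3 WT P22 replicate 1 they were 5 (Nhlh1, Cda, As3mt, Oprl1 and Elavl2), and leaving out other single libraries gave 6 to 12. Nhlh1 and Cda were also called higher in all 3 marks after centring, whereas Arc and Oprl1 were then called lower in H3K27ac. Both cKO libraries lay above both WT libraries at 16 of 23 promoters for H3K4me3 and at 22 of 23 for each acetylation mark. Both lay below at 1 for H3K4me3, Hmcn2, and at 0 for each acetylation mark. Chance gives 16.7% in 1 direction for a single promoter, but a shift common to most promoters moves these counts together, so this is no test of the counts. The mean score over the 23 promoters went from 6.56 ± 1.98 to 15.8 ± 6.69 for H3K4me3, from 3.09 ± 0.66 to 8.49 ± 2.57 for H3K9/14ac and from 3.35 ± 0.56 to 8.93 ± 1.53 for H3K27ac (SD, n = 2). The ratios of 2.40, 2.75 and 2.67 depend on where the score has its zero, which the sources used here do not state. An exact two-sided permutation test of the library means gave p = 0.33 for each mark, which is the smallest value that 2 libraries against 2 allow. Replicates differed by a shift common to most promoters: replicate 2 of the H3K4me3 cKO libraries was higher than replicate 1 by a median of 0.68 on the log2 scale. Limma treats promoters as independent and pooled the spread over them, so its adjusted p-values are too small where such shifts act. The size of the cKO change at a promoter was not shown to differ between marks. The interaction term of a limma fit on both marks called 0 of 22 promoters for each pair of marks (Benjamini-Hochberg adjusted), with 1 unadjusted p under 0.05 for H3K4me3 against H3K9/14ac, 2 for H3K4me3 against H3K27ac and 0 for the acetylation marks.

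The authors' mean curves show where around the TSS the marks differed at P22. Signal within 1000 bp of the TSS was 0.840 ± 0.168 in WT and 1.35 ± 0.38 in cKO for H3K4me3, a ratio of 1.61 ± 0.56. H3K9/14ac went from 0.418 ± 0.046 to 0.847 ± 0.177, a ratio of 2.03 ± 0.48. For H3K27ac the values were 0.451 ± 0.035 and 0.974 ± 0.096, a ratio of 2.16 ± 0.27. All ± values of the curves come from the authors' error columns, averaged over positions, which gives an upper limit to the deviation of a window mean. Ratios of the curves also depend on the unstated zero of the score. Each curve was highest just downstream of the TSS, at +135 bp in WT and +170 bp in cKO for H3K4me3, at +158 and +174 bp for H3K9/14ac, and at +137 and +164 bp for H3K27ac. The cKO to WT ratios of these maxima were 1.56, 1.98 and 1.92. At the TSS itself the ratios were 1.26, 1.68 and 1.75, whereas 1000 bp downstream they were 2.95, 2.92 and 3.24. At 1000 bp upstream H3K4me3 was near 0, at 0.027 in WT and 0.042 in cKO, and the acetylation ratios were 2.04 and 2.50. For H3K4me3 the ratio over the 1000 bp upstream was 1.14 ± 0.37 and over the 1000 bp downstream 1.82 ± 0.65. These ratios were 1.72 ± 0.31 and 2.22 ± 0.59 for H3K9/14ac, and 2.03 ± 0.18 and 2.25 ± 0.34 for H3K27ac. A difference between the sides was not tested. Between 1000 and 2000 bp downstream, H3K4me3 was 0.069 ± 0.018 in WT and 0.348 ± 0.111 in cKO, and the curves were farther apart than the sum of their errors at 1000 of 1000 positions. For H3K4me3 this held at 54.8% of positions within 1000 bp of the TSS, 26.9% within 500 bp and 32.7% over the 1000 bp upstream. Neighbouring positions of a mean curve are not independent, so these counts describe the curves and are no test.

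Averaged over the outermost 10% of the curves on both sides, H3K4me3 was -0.0029 in WT and -0.0015 in cKO, so no ratio of TSS to flank was formed. The 2 sides had opposite signs. The upstream level was 0.055 in WT and 0.052 in cKO, and the downstream level was -0.060 and -0.055. H3K9/14ac averaged over both sides was 0.086 ± 0.016 in WT and 0.144 ± 0.027 in cKO. H3K27ac was 0.101 ± 0.005 in WT and 0.219 ± 0.026 in cKO, a ratio of 2.16 that equals the ratio within 1000 bp of the TSS. The signal near the TSS relative to the flank was 1.21 times that of WT in the cKO for H3K9/14ac and 0.999 times for H3K27ac, both within their errors of 0.43 and 0.18. These errors treat the windows as independent, although they come from the same libraries. An equal rise near and far from the TSS is therefore not shown. No libraries are given separately in the curves, so no permutation test was made. The genes averaged are not given in the sources used here, and the column names carry no age, which was read as P22 because cKO libraries exist at that age alone. The input libraries were not analysed here.

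**Figure D2:**
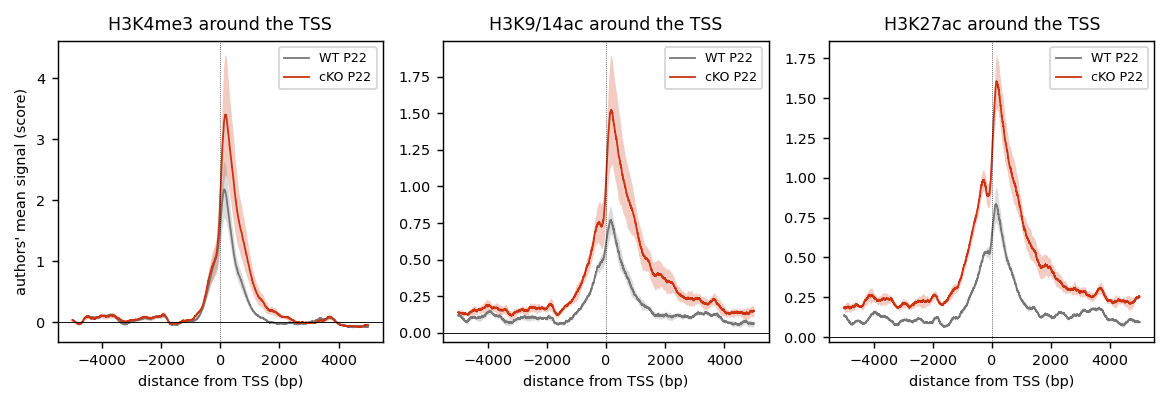
Authors' mean signal (vertical axes, score units) of H3K4me3, H3K9/14ac and H3K27ac from -5000 to 5000 bp around the TSS in WT P22 and cKO P22; shaded bands are the authors' error columns. For H3K4me3 the cKO curve exceeds the WT curve more downstream than upstream of the TSS, and the H3K27ac flank is 0.101 in WT and 0.219 in cKO.

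A further question was how these promoters change between P6 and P22 in WT mice, when granule neurons of the cerebellum mature. Chromatin came from cerebella rather than from a single cell type. Changes within cells, with age or in the cKO, cannot be told apart from changes in cell proportions. H3K4me3 fell with age at 3 of 19 promoters tested and rose at 2 (limma, Benjamini-Hochberg adjusted); Nt5dc2 was chosen for naming after its values were seen. At Nhlh1 H3K4me3 went from 43.5 ± 9.26 at P6 to -0.28 ± 0.31 at P22 (SD, n = 2 each), a log2 change of -4.72 ± 0.43 (SE) with limma adjusted p = 1.8e-14. Nt5dc2, for which only WT scores are in the table, went from 46.7 to 5.72, and Elavl2 from 4.43 to 0.24 (log2 changes -2.68 and -1.52). Arc rose from 4.74 to 16.4 (log2 change 1.43). H3K9/14ac fell at 2 of 23 promoters, Nt5dc2 (17.5 to 1.27) and Nhlh1 (11.3 to 0.46), by 2.58 and 2.45 on the log2 scale. It rose at 1, Arc, from 3.40 to 8.34, with a log2 change of 0.93 and limma adjusted p = 0.0116. Elavl2 scored 1.99 at P6 and 0.40 at P22 in H3K9/14ac, with limma adjusted p = 0.0623. Centred libraries gave 4 promoters higher and 6 lower at P22 for H3K4me3, and 1 higher and 5 lower for H3K9/14ac. Without WT P22 replicate 2, H3K4me3 had 3 calls, losing Arc and Elavl2; Arc was also lost without P6 replicate 1 and Elavl2 without P6 replicate 2, and in H3K9/14ac Arc was lost without WT P22 replicate 2 or P6 replicate 1. With a pseudocount of 20, or with the spread of each gene taken alone, H3K4me3 had 2 age calls, and H3K9/14ac had 1 with the latter; without a log scale each mark had 1. The table mean of 23 promoters was 0.78 times the P6 level for H3K4me3 and 0.90 times for H3K9/14ac, with exact two-sided permutation p = 0.667 for each.

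The last comparison asked whether promoters that lose a mark between P6 and P22 are those that gain it in the cKO. Of the promoters tested in both comparisons, the 2 whose H3K4me3 fell with age, Nhlh1 and Elavl2, both rose in the cKO, where 1 is expected of independent lists (exact two-sided Fisher p = 0.471). For H3K9/14ac it was 1 of 1, Nhlh1, with 0.82 expected and exact two-sided Fisher p = 1. Lists this short allow no Fisher p under 0.471 and 0.182, so these tests could not have passed. Arc went the other way with respect to age: it rose from P6 to P22 and rose in the cKO in both marks. Across promoters, which are not independent replicates, the fall with age and the rise in the cKO correlated with a Pearson r of 0.64 and a Spearman coefficient of 0.34 for H3K4me3 and with 0.64 and 0.45 for H3K9/14ac. All 18 promoters tested for H3K4me3 in the cKO and all 22 for H3K9/14ac had a change above 0. The share that also fell with age, by any amount, was 38.9% and 50%. As no promoter changed downward in the cKO, these shares carry no information on a link between the 2 changes. Both comparisons use the same WT P22 libraries, and unchanged groups simulated against shared controls gave r = 0.49 in each mark. The 95th percentiles of the simulated r, 0.757 and 0.737, lie above the observed r. Without real changes such an r arises at any size of spread. It therefore cannot show how much of the observed r comes from shared controls. The covariance was 0.875 for H3K4me3, against 0.0894 simulated, and 0.233 for H3K9/14ac, against 0.0363 simulated. Nhlh1 carried most of it: without Nhlh1 the covariances were 0.0783 and 0.0571 and r was 0.13 and 0.32. These r lie under the simulated value in both marks, and for H3K4me3 the remaining covariance does too, but neither shows an absent relation. The simulated spread held shifts common to the promoters of a library, which add nothing to a covariance across promoters. The simulated covariances are therefore too large. A split chosen after the data were seen gave each comparison 1 of the WT P22 libraries, so that none was shared. The covariances were then 0.739 or 0.937 for H3K4me3, depending on which library served which comparison, and 0.204 or 0.231 for H3K9/14ac. Without Nhlh1 they were -0.017 or 0.111 and 0.025 or 0.057. The covariance carried by the single promoter Nhlh1 thus remained without a shared library. Its WT P22 scores were near 0 in both libraries of each mark, so this split could hardly have removed it. Among the other promoters the covariance varied with the library used. Spearman coefficients over all promoters were 0.16 or 0.34 for H3K4me3 and 0.34 or 0.45 for H3K9/14ac. With single libraries on each side, part of the relation in the full data may still come from the shared controls.

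**Figure D3:**
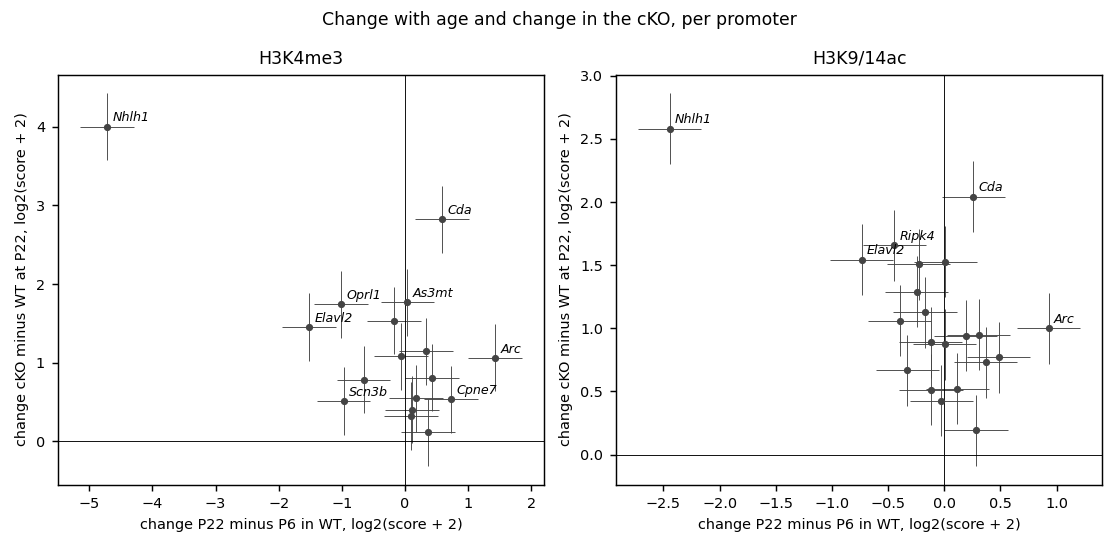
Change in the cKO at P22 (vertical axes) against change from P6 to P22 in WT (horizontal axes) for H3K4me3 and H3K9/14ac, both in log2(score + 2) units; each point is 1 promoter (1 promoter of the table is left out) and bars are limma standard errors. Nhlh1 stands apart from the other promoters in both marks, at -4.72 and 4.00 for H3K4me3.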

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

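The test of differences between marks and the naming of Nhlh1 here came after the changes in each mark had been seen. Between P6 and P22 in WT mice, the log2 change of Nhlh1 was -4.72 in H3K4me3 and -2.45 in H3K9/14ac. The interaction term of a limma fit on both marks was -2.28 ± 0.39 (SE), with adjusted p = 1.1e-04 (limma, Benjamini-Hochberg over 21 promoters). The P6 scores were 43.5 and 11.3, and both marks ended near 0, at -0.28 and 0.46. With a pseudocount of 2 the size of each fall is then set by the starting score, and the score scales of the 2 antibodies are not stated to be comparable. The difference therefore does not show that Nhlh1 lost more of one mark than of the other. Of the 21 promoters 2 passed, while 4 had an unadjusted p under 0.05.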

How the results depend on the processing

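Pseudocount 1, scores without log, each gene's own spread and centred libraries were chosen after the data were seen. Of 407 values of named promoters under alternatives other than scores without log, whose unit differs, 346 kept their direction and side of the threshold, 52 no longer passed, 3 newly passed and 6 reversed. The reversals all came with libraries centred on their median: Cplx3 in H3K4me3 (-0.12), Oprl1, Smoc1 and Arc in H3K9/14ac (-0.018, -0.084 and -0.15), and Cpne6 and Syde1 in H3K27ac (-0.015 and -0.062). With the replicate block, the 2 groups compared alone, each gene's own spread or no filter, log2 changes stay as in the main fit. The 37 values of each of these settings could not reverse. The 407 values cover only the promoters named in each comparison. Outside them, centring turned higher into lower calls at Cpne7, Gnb3 and Scn3b in H3K9/14ac. In H3K27ac it did so at promoters that include Arc, Oprl1, Pde1b and Timp2. Centring sets the median promoter near 0 by construction. It gave median genotype changes of 4.7e-04, -0.20 and -0.11 for H3K4me3, H3K9/14ac and H3K27ac, with 5, 10 and 11 genotype calls, and 10 and 6 age calls for H3K4me3 and H3K9/14ac. A pseudocount of 20 compressed the median genotype changes to 0.32, 0.29 and 0.29 and gave 5 genotype and 2 age calls for H3K4me3; with a pseudocount of 1 the H3K27ac median was 1.26. Without log, H3K4me3 had 0 genotype calls, losing all 9 including Nhlh1 and Cda (limma, 5 at an unadjusted p under 0.05) and 1 age call, and H3K9/14ac 1 age call; the cause was not tested. With each gene's own spread, which rests on fewer degrees of freedom, genotype calls were 3, 11 and 8 and age calls 2 and 1. Leaving out each library in turn gave 5 to 12, 10 to 20 and 15 to 20 genotype calls, 3 to 5 and 2 to 4 age calls, and median genotype changes of 0.49 to 1.31, 0.67 to 1.19 and 0.84 to 1.26. The titles number the libraries B1 and B2, and no label says whether B stands for batch or for biological replicate. With the replicate block, H3K4me3 had 15 genotype and 10 age calls, H3K9/14ac 21 and 7, and H3K27ac 18 genotype calls. In the genotype comparisons it newly called Duox2, Pde1b and Timp2 in H3K9/14ac and, among others, Cplx3 in H3K4me3. In H3K27ac it lost Pde1b and Timp2. Deviations of same-numbered libraries correlated at 0.74, 0.22 and -0.29 between genotypes and at 0.37 and 0.10 between ages. Other windows, flanks and smoothing moved no curve ratio by more than its error. The planned fits on read counts, a pseudocount of 0.2 (scores go below it), tests of separate libraries in the curves and tests of the inputs were not run.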

Other observations

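The tests of a single factor, of curve shape and of flanking level, and the comparison of cKO P22 with WT P6, were chosen after related results were seen; the test with centred libraries against P6 was set before its result. In H3K4me3, the cKO at P22 exceeded the WT level at P6 at 9 of 18 promoters and was lower at 0 (limma, Benjamini-Hochberg adjusted; 9 had an unadjusted p under 0.05). Cda scored 0.06 at P6 and 20.9 in the cKO, Arc 4.74 and 38.5, and As3mt 2.66 and 14.6. H3K9/14ac was higher in the cKO than at P6 at 17 of 22 promoters. For Nhlh1 and Elavl2, which lost H3K4me3 with age, the P6 and cKO scores were 43.5 and 26.0 (limma adjusted p = 0.143) and 4.43 and 4.15 (limma adjusted p = 0.878). In H3K4me3 both Nhlh1 cKO libraries lay below both P6 libraries, and after centring Nhlh1 and Elavl2 were called lower in the cKO than at P6. In H3K9/14ac the P6 and cKO scores were 11.3 and 12.7 for Nhlh1 (limma adjusted p = 0.631) and 1.99 and 4.98 for Elavl2 (limma adjusted p = 0.00862), and after centring only Nhlh1 of this pair was called lower. Before centring, the median log2 change of the cKO against P6 was 0.87 in H3K4me3 and 1.00 in H3K9/14ac. A lower call after centring means a smaller change than that of the library medians, which by itself is no lower score. Scores that did not pass the test as deposited do not show equal levels either, so a return to the P6 level is not shown.

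Casq1, Gnb3 and Cpne6 were under the H3K4me3 filter, with no library above a score of 1.65, and their H3K27ac rose in the cKO from 1.67 to 10.2, from 3.27 to 11.6 and from 0.47 to 3.54. Without the filter their H3K4me3 changes were 0.84, 0.49 and 1.13 on the log2 scale (limma adjusted p = 0.0633, 0.192 and 0.0115), so Cpne6 rose in H3K4me3 too. The H3K4me3 changes minus those of H3K27ac were -0.86, -0.88 and -0.028 (limma interaction, adjusted p = 0.311, 0.308 and 0.949), and a difference between the marks was not shown.

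The first pattern is the rise of scores at most promoters in the cKO, and a technical candidate explanation is a scale factor between libraries, since the authors' scaling is not stated. As the whole cause it is argued against by the spread of the changes: squared distances from the best single factor were at least 7.90 times their expected value in each mark. Without Nhlh1 and Cda they were still at least 2.34 times the expected value. A smaller factor acting on top of unequal changes, or a factor joined to a different subtraction of background, stays open, because the table holds none of the 10 housekeeping genes listed beforehand and no promoter known to be unchanged. The loss of Chd4 stays among the open explanations.

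The second pattern is the shape of the curves. If a single factor were the cause and the zero of the scores were true, the cKO to WT ratio would be equal at every distance, but for H3K27ac it was 1.96 within 500 bp and 3.23 between 1000 and 2000 bp downstream, an excess of 2.50 errors on the log2 scale. For H3K9/14ac the excess was 1.35, within the 2 errors asked for. The errors here and in the next test treat windows as independent, although they come from the same libraries. An excess under 2 errors therefore does not show an equal ratio. For H3K4me3 no ratio is used, since its downstream flank was -0.060 in WT, about as far from 0 as the level of 0.069 between 1000 and 2000 bp. A factor joined to an offset, which does not need a true zero, would put this level on a line through flank and core. It lay above that line by 1.94 to 2.49 errors for H3K27ac, 1.52 to 2.31 for H3K4me3 and 1.27 to 1.93 for H3K9/14ac, depending on the flank and core used. The bound, over 2 errors in every mark for each flank and core, was set with the curve levels known. An earlier bound, over 2 errors in any mark with a single flank and core, had been exceeded by H3K27ac at 2.32. The outcome turns on the bound, so a factor with an offset and a change of shape cannot be told apart. The average rise of H3K27ac within 1000 bp was nevertheless of the same proportion as in the flank (0.999) if the zero is true. By window its cKO to WT ratio was 1.96 within 500 bp, and 2.55 upstream and 3.23 downstream between 1000 and 2000 bp. In the flank the ratio was 2.00 upstream and 2.33 downstream. An even rise over the whole 5000 bp on either side is therefore not shown. A rise that reaches the flank may still be part of the H3K27ac level near the TSS. Whether the rise in the flank is background or acetylation outside promoters was not tested, as the inputs were not analysed here.

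The third pattern is the cKO level above P6. With centred libraries 4 promoters in H3K4me3 (among them Arc, As3mt and Cda) and 2 in H3K9/14ac (Arc and Cda) were higher in the cKO. Relative to the library medians, 5 in H3K4me3 (Elavl2, Nhlh1, Pde1b, Scn3b and Smoc1) and 9 in H3K9/14ac, among them Nhlh1, were lower. A scale factor and a gain beyond the P6 level cannot be told apart for the other promoters, because at least 3 in each mark had been asked for and H3K9/14ac kept 2. A hypothesis left by these values is that Cda carries more of both marks without Chd4 than at either age in WT, as it was called in both comparisons with and without centring. Arc may be above its P6 level, but after centring it differed from WT P22 by 0.13 in H3K4me3 and -0.15 in H3K9/14ac. Its H3K27ac was then called lower in the cKO than in WT P22.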
